A study of Mus musculus with 2 samples.

How the data were processed

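Chromatin accessibility was measured by droplet single-cell ATAC-seq in bone marrow cells of 2 mouse groups, wild type (WT) and Irf8cKO, in which a floxed Irf8 gene is recombined by Cre expressed from Csf1r regulatory sequence. In this assay the Tn5 transposase cuts open chromatin inside nuclei, and both ends of each sequenced fragment mark a cut site. Per the labels' protocols, marrow was flushed from femurs and tibias of mice aged 8 to 12 weeks, erythrocytes were lysed, and live single cells were sorted by exclusion of a viability dye. There was 1 library per group, so no difference has a replicate check, and no p-value or standard error was computed.

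The authors deposited 1 fragment list per library, with chromosome, start, end and barcode of each distinct fragment and, in column 5, the count of read pairs behind it, as read from the file values. The deposited counts are not normalized. Cell Ranger ATAC 1.0.1, Signac 1.14.0 and the build mm10 are named in the submitters' processing notes, which do not say which step used which tool. Aligner settings and duplicate marking are not given in the sources used here. The lists carry no cell calls and no cell annotation, so cells were called and named anew. The WT list held 68643077 fragments from 184646478 read pairs and the Irf8cKO list 77983732 fragments from 193171596 read pairs. The offset between abutting cut sites of different fragments on chromosome 1 was most often 0 bp in both libraries (377486 and 369128 pairs), so starts and ends were used as deposited, with no further shift.

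A barcode was kept as a cell with at least 2000 and at most 100000 nuclear fragments and a transcription start site (TSS) enrichment of at least 4. TSS enrichment was the cut site density within 50 bp of protein-coding TSSs over that 1900 to 2000 bp away. Gene positions came from a RefSeq table of the mouse assembly GRCm38, the assembly that mm10 names, with 21631 protein-coding genes. The table gives no strand, so the gene end with more cut sites within 500 bp was taken as the TSS. That end held over 2 times the cut sites of the other end at 72.3% of genes. Likely doublets were ranked by the share of simulated doublets among nearest neighbours, and a share of 0.8% for each 1000 cells was left out, 34 in WT and 19 in Irf8cKO. This left 2041 WT and 1529 Irf8cKO cells. The upper limit removed 47 WT and 169 Irf8cKO barcodes.

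Cells of both libraries were clustered together on 5 kb bins by TF-IDF weighting, singular value decomposition (30 components, of which 29 were used), a graph of 15 nearest neighbours and the Leiden algorithm at resolution 1, which gave 24 clusters. Clusters were named from 17 marker sets by the mean log2 accessibility of the markers over the lower quartile of clusters. Among sets within 0.75 of the best score, the one with most markers among the 10 leading genes was taken. This scoring rule was set after seeing the data. A cluster with under 3 open markers, with shallow cells and no own marker among its leading genes, or with markers of 2 mature lineages stayed unnamed, which applied to cluster 21. All names are therefore marker-based likenesses and not sorted populations. The B cell class held a cluster led by more dendritic cell markers than B cell markers, so its clusters are given by number, and the pro- and pre-B cell class took its place as the class outside the myeloid lineage. The erythroid class was added as a further comparison after seeing the data.

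Gene accessibility was the number of fragments overlapping the gene body and 2 kb upstream, summed over the cells of a class and given per 1000000 such fragments. Each ratio, Irf8cKO over WT, has a 95% interval from the exact conditional binomial distribution of 2 Poisson sums. Shares of cells have exact Clopper-Pearson 95% intervals. All intervals cover counting error only, and a count of 0 was taken to allow up to 3 counts. There were 17 comparison gene lists. A list was described by the median log2 ratio of its members with at least 200 fragments (0.5 added to each sum) and by the percentile of that median among 10000 random lists of the same size matched on mean accessibility. Percentiles below 2.5 or above 97.5 were called outside the random range. All members of the late granule, B cell and erythroid lists also belong to the marker sets that named the clusters. So do most members of the primary granule and the monocyte and macrophage lists. Random lists are thus no neutral reference for these lists, whose percentiles are descriptive. Of the listed genes, 2 (Mx1 and Mx2) had no protein-coding entry in the gene table.

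The rule for naming genes took the 10 highest and 10 lowest ratios whose 95% interval lay beyond 1.5-fold, among genes with at least 200 fragments in the class and 10 in each library. It also took, per list, the 4 members with the largest absolute log2 ratio and the 4 most accessible ones, and always Irf8 and Csf1r. Not every gene that the rule allows is printed. The marker sets, gene lists, this rule and the cell limits other than the upper one were fixed before the data were examined. At Irf8, the longest stretch of the gene without a cut site was located in each library. At Csf1r, neighbouring 500 bp bins around the gene start with over 2 times the WT level in all kept cells were joined into 1 window. Both intervals were defined after seeing the data. The gene table gives no exons, so positions are given without exon numbers. Peaks and motifs were left out because no genome sequence was used here.

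Ratios, the naming rule and list percentiles were tested on simulated sums for 12959 genes of the promyelocyte class, of which 12767 were unchanged and 48, 49, 48 and 47 were changed 1.5-fold, 2-fold, 3-fold and 4-fold. Intervals held the true ratio for 95.6% of unchanged genes. The size rule recovered 2.08% of genes changed 1.5-fold, 93.9% of those changed 2-fold and 100% of those changed 3-fold or 4-fold, and it took 0% of unchanged genes. Of 200 simulated lists of unchanged genes, 6% fell outside the random range. Both simulated sums were Poisson draws from a shared profile, the model that the intervals assume, without variation between clusters, cells or mice. The simulation therefore checks the calculation and not whether named genes or lists differ by genotype. Alternatives set beforehand varied the fragment minimum, the TSS minimum, doublet removal, the clustering, the scaling, the gene window, the weight of cells, duplicates and the gene filter. Added after seeing the data were alternatives on the upper fragment limit, on ratios within clusters and finer clusters, and on the pro- and pre-B and erythroid cells lowest in late granule fragments. Tools were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, igraph 0.11.9, leidenalg 0.10.2 and matplotlib 3.10.9.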

Results

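Single-cell chromatin accessibility was compared between whole bone marrow of WT mice and of mice in which Irf8, a transcription factor needed for monocyte and dendritic cell development, was deleted through Csf1r-Cre. Csf1r encodes the receptor for macrophage colony-stimulating factor, on which monocytes, macrophages and osteoclasts depend. The series title places the question in osteoclast formation from marrow precursors. There was 1 library per group, with 2041 WT and 1529 Irf8cKO cells kept. Median depth over all kept cells was close, at 23238 fragments per cell in WT and 22761 in Irf8cKO, and median TSS enrichment was 28.1 and 28.8. Within classes, depth was close in neutrophils (19687 and 19478.5) and promyelocytes (42089.5 and 45933.5). It was lower in Irf8cKO in monocytes (37109.5 and 9385) and stem and early progenitor cells (36788 and 25496). It was higher in pro- and pre-B cells (24855 and 38743) and erythroid cells (13575 and 20208). Differences below describe these libraries and have no replicate check, and intervals cover counting error only.

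The targeted gene was examined first. Irf8 (gene ID 15900) lies on chromosome 8 from 120736358 to 120756694 (mm10). In the Irf8cKO library it held a stretch of 1162 bp, from 120739072 to 120740233, without a single cut site in any barcode, where WT had 129. The next longest empty stretch of Irf8cKO in the gene was 210 bp, and the longest of WT was 85 bp. In addition, 9 Irf8cKO fragments of 1345 to 1669 bp spanned the whole stretch, against 0 in WT. Without the stretch, the lengths of these fragments were 183 to 507 bp. Fragments over 1000 bp within 20 kb of the gene numbered 11 in Irf8cKO and 7 in WT.

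In kept cells the stretch held 95 WT cut sites and 0 in Irf8cKO. The WT cut sites came from plasmacytoid dendritic cells (59), monocytes (21), clusters 15 and 18 (9) and pro- and pre-B cells (6), classes with fewer cells in Irf8cKO. Taking each class's WT rate, 4.57 cut sites were expected in Irf8cKO, and the count of 0 allows up to 3. The stretch was chosen as empty in Irf8cKO, so this 0 was fixed in advance and the expected value gives scale only. That value also counts the neutrophil fragments estimated in pro- and pre-B droplets as fragments of pro- and pre-B cells. Neutrophils and promyelocytes had 0 cut sites there in both libraries, so within these classes the state of the stretch was not detectable at this depth. Outside the stretch Irf8 remained accessible in Irf8cKO, and in promyelocytes the rest of the gene had 8.48 times the WT cut site level (95% interval 5.84 to 12.7; 396 against 30 cut sites). This value also describes the make-up of the class, since within finer clusters the ratio of the whole gene was 2.44 (0.887 to 6.72). For the rest of the gene the ratio was 2.34 (1.72 to 3.18) in stem and early progenitor cells, 1.86 (1.21 to 2.94) in neutrophils and 0.691 (0.642 to 0.744) in pro- and pre-B cells. The Irf8cKO droplets of the last class held an estimated 36.8% neutrophil fragments, and in its cells below the median share of late granule fragments the ratio of the whole Irf8 gene was 1.07.

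**Figure D1:**
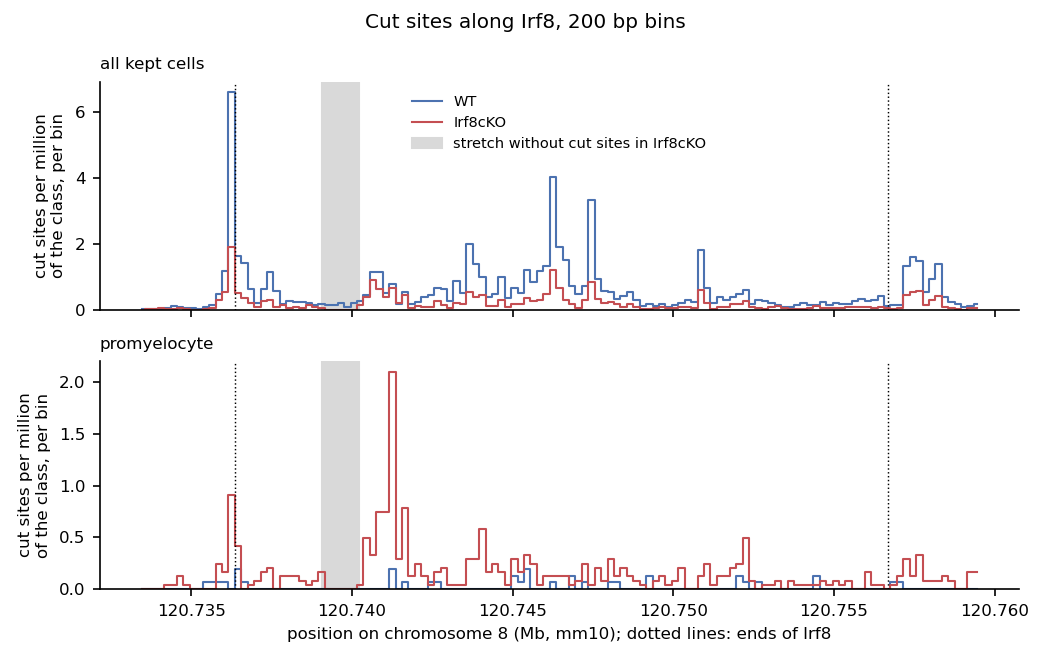
Cut sites per 1000000 cut sites of the cells plotted, in 200 bp bins (y axis), along chromosome 8 in Mb (x axis), for WT and Irf8cKO, over all kept cells and over promyelocytes. Irf8cKO shows 0 cut sites in the shaded 1162 bp, and in promyelocytes it lies above WT over most of the rest of the gene.

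Cell classes differed widely in share. Granulocytes, the sum of the promyelocyte and neutrophil classes, made up 45.2% of WT cells (95% interval 43.0 to 47.4%) and 87.2% of Irf8cKO cells (85.5 to 88.9%). Promyelocytes, which carry primary granule genes, were 8.33% in WT and 16.7% in Irf8cKO, and neutrophils 36.8% and 70.5%. The line between both classes rests on cluster 11 (129 WT and 12 Irf8cKO cells), which was placed with promyelocytes by its leading genes but scored higher for neutrophil (2.46) than for promyelocyte markers (2.12). With at least 5000 fragments per cell the matching cluster was named neutrophil, and promyelocytes were 2.52% and 14.0% (ratio 5.57 against 2.01). Promyelocytes formed no class of their own in the space fitted on WT cells. Monocytes were 9.60% of WT cells (8.36 to 11.0%; 196 cells) and 0.458% of Irf8cKO cells (0.184 to 0.941%; 7 cells), a ratio of 0.0477. That ratio was 0.115 (17 Irf8cKO cells) with the space fitted on WT cells and 0.0281 with at least 5000 fragments per cell. Plasmacytoid dendritic cells, the main producers of type I interferon, numbered 49 in WT and 1 in Irf8cKO (2.40% and 0.0654%), a ratio of 0.0272. With at least 1000 fragments per cell they numbered 52 and 6 (ratio 0.151), and with no upper limit 51 and 3 (0.0725).

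Lymphoid and erythroid classes were also smaller shares of the Irf8cKO library. Pro- and pre-B cells were 16.5% (14.9 to 18.2%) and 6.87% (5.65 to 8.25%), erythroid cells 12.8% (11.4 to 14.4%) and 2.42% (1.71 to 3.32%), and T and NK cells 2.25% and 0.654%. Basophils and mast cells were 1.03% and 0.327%, and stem and early progenitor cells 1.76% (36 cells) and 1.37% (21 cells). Of the clusters with B cell markers, cluster 15 held 84 WT cells and 1 Irf8cKO cell, and cluster 18 held 52 and 3. The unnamed cluster 21, kept out of the classes by a rule set after seeing the data, held 1.76% of WT and 0.327% of Irf8cKO cells.

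Shares within 1 library are not independent of each other, so classes were also expressed among the 1119 WT and 195 Irf8cKO cells outside the granulocyte classes. Monocytes were then 17.5% and 3.59% (ratio 0.205), pro- and pre-B cells 30.1% and 53.8% (ratio 1.79), and erythroid cells had a ratio of 0.810 (0.558 to 1.15). Stem and early progenitor cells were 3.22% and 10.8%. With no upper limit on fragments per barcode the ratio of pro- and pre-B cells turned to 0.811, and that of erythroid cells was 0.522. With the space fitted on WT cells the ratio of monocytes was 0.501 (0.286 to 0.823). Erythrocyte lysis and the sort for live cells can set the erythroid share.

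**Figure D2:**
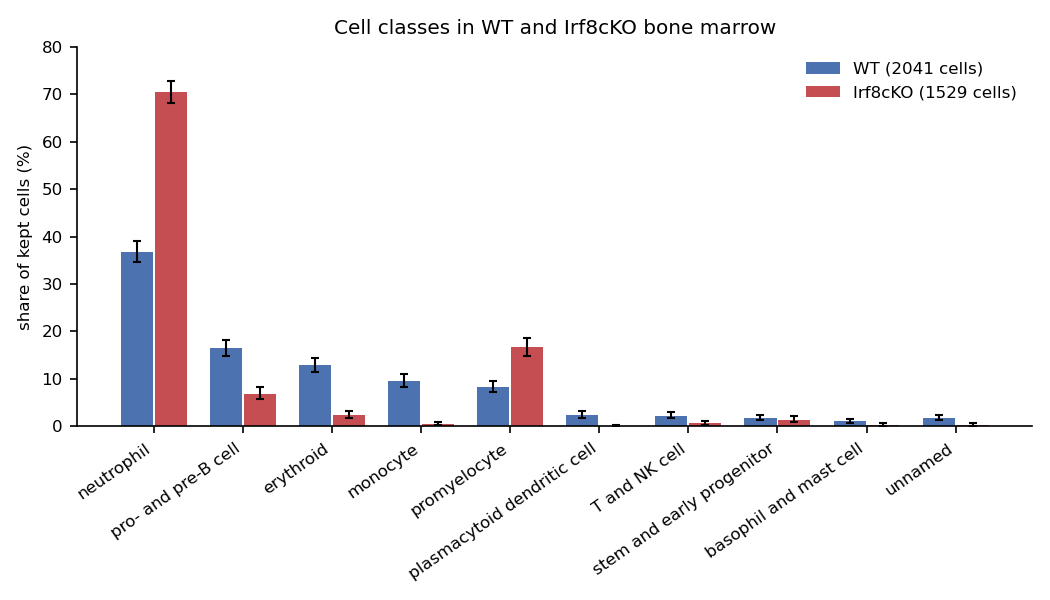
Share of kept cells in percent (y axis) for each cell class (x axis) in WT (2041 cells) and Irf8cKO (1529 cells), with exact 95% binomial intervals that cover counting error only. The B cell class (clusters 15 and 18) is not drawn. The neutrophil and promyelocyte bars are higher in Irf8cKO and the bars of the monocyte, plasmacytoid dendritic cell, pro- and pre-B cell and erythroid classes are lower.

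Monocytes depend on Csf1r, and osteoclasts can derive from them. The 7 remaining Irf8cKO monocytes held 93519 fragments against 7767476 in 196 WT monocytes, so most ratios were wide. Their median depth was 9385 fragments per cell, against 37109.5 in WT. The monocyte and macrophage list had a median log2 ratio of -0.11 (percentile 17.8), with 4 of 17 members over 1.5 times higher and 8 over 1.5 times lower. The osteoclast differentiation and function list had a median of 0.31 (percentile 76.6), with 4 of 13 members over 1.5 times higher and 3 lower. In promoter windows these medians were 0.34 and 1.10. Klf4, a monocyte transcription factor, had a ratio of 0.414 (0.0852 to 1.22). F13a1, which encodes coagulation factor XIII subunit A, had 1.61 (1.11 to 2.26), Mitf, a transcription factor of osteoclasts, 1.67 (32 fragments against 1628; 0.951 with the space fitted on WT cells, where F13a1 had 0.891), and Nfatc1, the transcription factor that drives osteoclast formation, 0.972 (0.554 to 1.58; 1.73 in promoter windows, from 1 Irf8cKO fragment, and 1.57 thinned to 2000 fragments per cell). Irf8 had 1.73 (0.915 to 2.98) and Csf1r 1.81 (1.07 to 2.88).

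The Toll-like receptor and inflammasome list had a median of -0.52 (percentile 2.08), with 7 of 13 members over 1.5 times lower and 3 higher, and the AP-1 list -0.41 (percentile 0.5), with 4 of 9 lower and 2 higher. These were the monocyte lists outside the random range. Their direction did not hold in promoter windows, where the medians were 0.15 and 0.30, or, for the Toll-like receptor list, with cells thinned to 2000 fragments (0.60). Neutrophil late granule genes, a sign of neutrophil fragments in these droplets, had a median of -0.08 (percentile 43.1; 1.07 in promoter windows).

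In promyelocytes, the highest ratio was that of Pld4, a lysosomal nuclease of myeloid and plasmacytoid dendritic cells (gene ID 104759, chromosome 12, 112760446 to 112768986), at 16.4 (8.75 to 34.5; 250 fragments against 10). Irf8 followed with 8.35 (5.10 to 14.6) and Tmem178, a regulator of calcium in osteoclast precursors (gene ID 68027, chromosome 17, 80944632 to 81001816), with 7.98 (5.67 to 11.5). The others of the 10 highest were Hhipl1 (5.46), Myo18b (5.30), Tgm6 (4.96), Ephb2 (4.48), Dusp22 (4.18), Shisa2 (4.04) and Htra3 (3.97). Not among these were Tnfrsf11a and Csf1r, named from the osteoclast list and by rule. Tnfrsf11a, which encodes RANK, the receptor for the osteoclast differentiation factor RANKL (gene ID 21934, chromosome 1, 105780673 to 105849444), had 3.46 (2.56 to 4.77) and Csf1r 3.05 (2.68 to 3.49), the latter through a window around the gene start, since the rest of that gene had 1.16 (0.964 to 1.40). With at least 5000 fragments per cell the ratios were smaller, at 6.02 for Pld4, 3.66 for Irf8, 4.54 for Tmem178 and 1.34 for Ephb2. With no upper limit on fragments they were 4.29 for Pld4, 3.48 for Irf8, 2.10 for Tmem178, 1.42 for Tnfrsf11a, 1.37 for Tgm6 and 1.13 for Ephb2, and Myo18b turned to 0.911. Shisa2 had 1.02 when each cell was thinned to 2000 fragments.

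Among the 10 lowest promyelocyte ratios were Asns, which encodes asparagine synthetase (gene ID 27053, chromosome 6, 7675165 to 7693209; ratio 0.251, 0.199 to 0.313), Bmpr1a, a receptor for bone morphogenetic proteins (0.305, 0.253 to 0.367), Arhgap44 (0.310, 0.246 to 0.388), Sec16b (0.402) and Cd55, a complement inhibitor (0.402; 0.827 with no upper limit). The class consisted of cluster 2 (41 WT and 244 Irf8cKO cells) and cluster 11 (129 and 12 cells), so the libraries were drawn from different clusters. Tmem178 and Ctsg are among the leading genes of cluster 2, and Asns and Arhgap44 among those of cluster 11, so that split can enter their values. Of these genes, Asns and Ctsg were nearer 1 within clusters, while Tmem178 and Arhgap44 were not. Within clusters, the Mantel-Haenszel ratio was 11.1 for Tmem178, 12.9 for Pld4, 8.24 for Irf8, 2.93 for Tnfrsf11a, 0.384 for Asns and 0.282 for Arhgap44. Within finer clusters of the same cells it was 5.48 (3.15 to 9.54) for Tmem178, 6.02 (2.99 to 12.1) for Pld4 and 2.44 (0.887 to 6.72) for Irf8, and within the clusters made with at most 50000 fragments Irf8 turned to 0.392. The gene windows of Arhgap44 and Elac2 overlap.

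By list, the osteoclast differentiation and function genes had a median log2 ratio of 0.13 in promyelocytes (percentile 99.2), with 2 of 15 members over 1.5 times higher and 0 lower. Mitf had a ratio of 1.49 (1.35 to 1.65) and Nfatc1 1.00 (0.940 to 1.07). Neutrophil primary granule genes had a median of 0.30 (percentile 99.2), with 2 of 7 members over 1.5 times higher. Ctsg, cathepsin G, had 2.33 (1.87 to 2.92; 1.55 within clusters and 1.47 with at least 5000 fragments per cell), Mpo, myeloperoxidase, 1.29 (1.13 to 1.47), and Bpi 0.776 (0.645 to 0.935). Late granule and maturation genes had a median of -0.21 (percentile 0.02), with 2 of 16 members over 1.5 times lower, among them Ltf, lactoferrin, at 0.624 (0.587 to 0.663) and Ly6g at 0.606 (0.509 to 0.722), while Ngp had 0.818 (0.758 to 0.882). The direction of the late granule list turned to 0.02 with at least 5000 fragments per cell, where the mostly WT cluster was named neutrophil and Ly6g had 1.10. It turned to 0.23 with no upper limit. The osteoclast list had a median of 0.0023 in promoter windows. With at most 50000 fragments it turned to -0.01, where 11 members were deep enough (0.02 with the 15 members used otherwise).

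The monocyte and macrophage list had a median of 0.04 in promyelocytes (percentile 67.8), with 4 of 13 members over 1.5 times higher, among them Klf4 at 2.43 (1.73 to 3.49) and F13a1 at 1.72 (1.53 to 1.94). Klf4 turned to 0.407 when each cell was thinned to 2000 fragments, and F13a1 to 0.949 with no upper limit. Of the Toll-like receptor and inflammasome list (0.14, percentile 92.3), 4 of 15 members were over 1.5 times higher, among them Aim2 at 2.05 (1.80 to 2.35) and Nlrp3 at 1.93 (1.61 to 2.33), sensors that assemble inflammasomes. The windows of Aim2 and Cadm3 overlap. The remaining promyelocyte lists lay within the random range, with medians from -0.17 (T and NK cell) to 0.17 (MHC class II presentation). The interferon response list had -0.10, the dendritic cell list -0.13, MHC class I presentation 0.02, complement and phagocytosis 0.04, myeloid transcription factors 0.03, negative regulators of osteoclast differentiation 0.03, AP-1 0.01, B cell 0.09 and housekeeping -0.03.

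**Figure D3:**
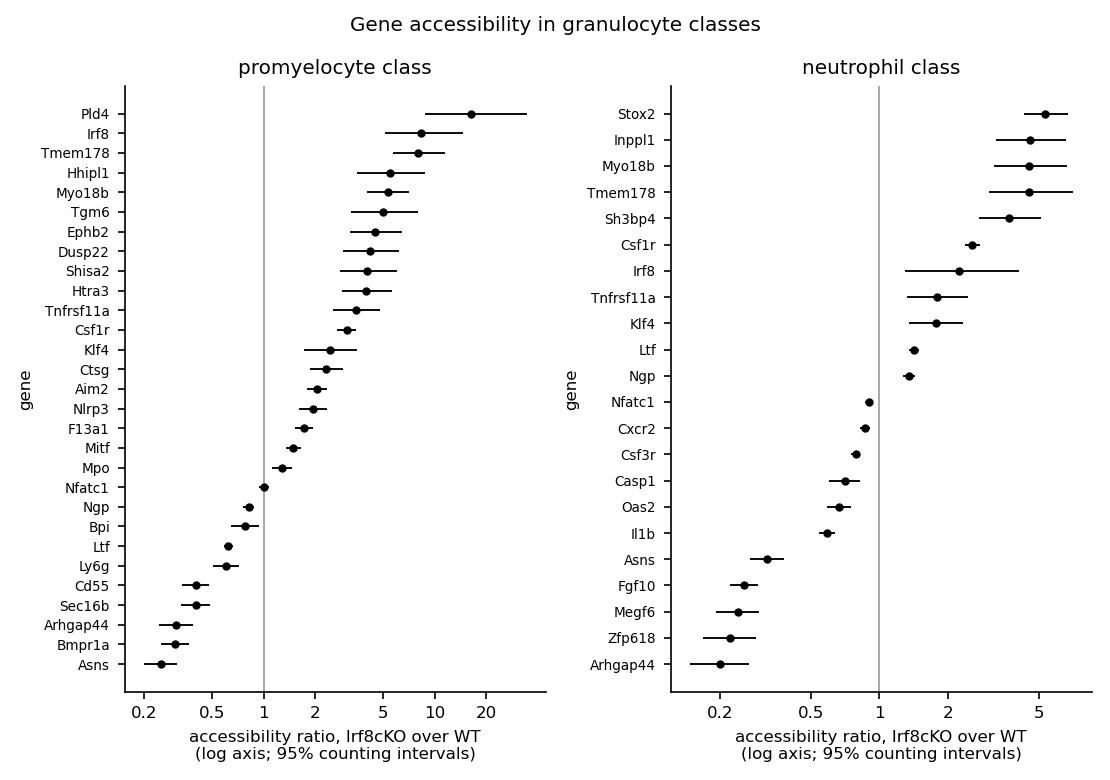
Accessibility ratio, Irf8cKO over WT, on a log axis (x axis) for named genes (y axis) in the promyelocyte and neutrophil classes, 1 library per group, with 95% intervals that cover counting error only. Pld4, Irf8 and Tmem178 are highest in promyelocytes, and Asns and Arhgap44 are low in both classes.

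In neutrophils, 1078 Irf8cKO and 752 WT cells gave the deepest comparison, and differences were smaller over most lists. Stox2 had a ratio of 5.33 (4.29 to 6.68), Inppl1, an inositol phosphatase, 4.55 (3.24 to 6.56), Myo18b 4.55 (3.19 to 6.67), Tmem178 4.53 (3.02 to 7.04) and Sh3bp4 3.71 (2.75 to 5.11). Over all settings Stox2 ranged from 4.32 to 7.29, Inppl1 from 2.88 to 7.61 and Myo18b from 3.34 to 9.32. The lowest Inppl1 value came from the space fitted on WT cells, where the class held all granulocytes. Tmem178 ranged from 2.07 to 14.5 and Sh3bp4 from 2.19 to 4.93. The gene window of Inppl1 overlaps those of Folr2 and Phox2a. On the low side were Arhgap44 (0.200, 0.147 to 0.268), Zfp618 (0.221), Megf6 (0.239), Fgf10, a growth factor (0.256), and Asns (0.321, 0.270 to 0.380). Within clusters Megf6 had 0.502 and Zfp618 0.375. Asns, Bmpr1a and Ltf are among the leading genes of cluster 10, which held 137 WT and 11 Irf8cKO cells. In contrast, cluster 4 (32 and 229 cells) and cluster 12 (2 and 138 cells) were mostly Irf8cKO and cluster 20 (40 and 4 cells) mostly WT. The Irf8cKO cells of cluster 12 were deep, with a median of 56724 fragments, against 19478.5 in all Irf8cKO neutrophils.

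Late granule and maturation genes, all of them markers used to name clusters, had a median log2 ratio of 0.14 in neutrophils (percentile 100), with 0 of 16 members beyond 1.5-fold. Ltf had a ratio of 1.41 (1.34 to 1.49) and Ngp 1.35 (1.27 to 1.43), whereas the receptors of late neutrophils, Csf3r and Cxcr2, had 0.787 (0.749 to 0.826) and 0.864 (0.823 to 0.908). The direction of this list did not hold within clusters (Mantel-Haenszel median -0.01) or in a space fitted on WT cells (-0.03). In that space the neutrophil class held all granulocytes (921 WT and 1337 Irf8cKO cells), so its values are not of neutrophils alone. The osteoclast differentiation and function list had a median of 0.06 (percentile 89.5), with Tnfrsf11a at 1.79 (1.33 to 2.44) and Nfatc1 at 0.904 (0.869 to 0.941). The Toll-like receptor and inflammasome list had -0.05 (percentile 3.47), with Il1b, interleukin 1 beta, at 0.589 (0.542 to 0.640) and Casp1, the protease that matures it, at 0.704 (0.601 to 0.825). The window of Casp1 overlaps Casp4, and that of Csf3r overlaps Mrps15. Oas2, of the interferon response list, had 0.668 (0.592 to 0.754), and Klf4 1.77 (1.35 to 2.33). Irf8 had 2.23 (1.29 to 4.07; 63 fragments against 17) and Csf1r 2.55 (2.36 to 2.75). The Irf8 ratio was higher at a TSS enrichment of at least 7 (4.86), with doublets kept (4.52) and in promoter windows (6.98). In the space fitted on WT cells it was 5.23, a value of all granulocytes, promyelocytes included.

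**Figure D4:**
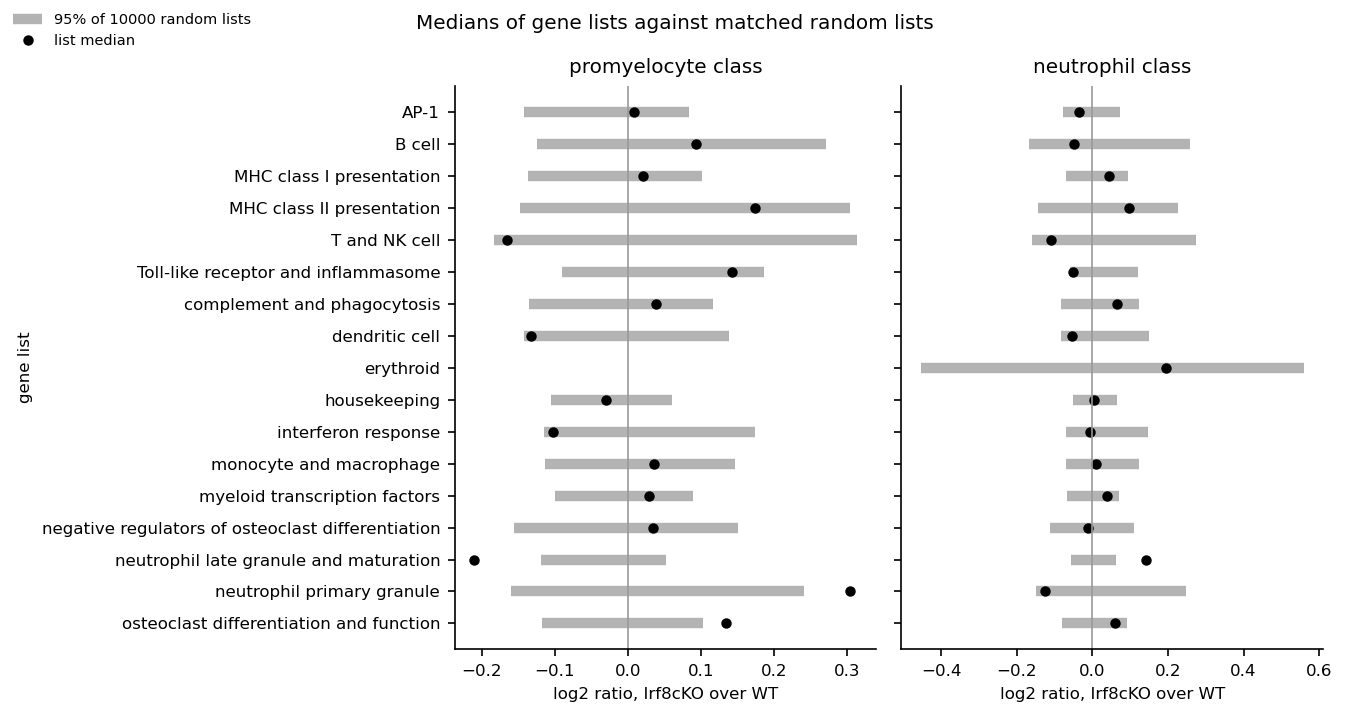
Median log2 ratio, Irf8cKO over WT (x axis, points), of the fixed gene lists (y axis) in the promyelocyte and neutrophil classes, with bars for the central 95% of 10000 matched random lists. Only the late granule list (both classes) and the primary granule and osteoclast lists (promyelocytes) lie outside the bars. Both granule lists share members with the markers that named the classes.

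Stem and early progenitor cells were few (36 and 21 cells), with 1382 genes deep enough. Mllt3, a regulator of stem cell maintenance, had a ratio of 0.400 (0.274 to 0.570), Angpt1, angiopoietin 1, 0.428 (0.324 to 0.559) and Tmem108 2.34 (1.78 to 3.09). In promoter windows Mllt3 and Angpt1 each had 10 Irf8cKO and 27 WT fragments, a ratio of 0.784 (0.339 to 1.67). Irf8 had 1.95 (1.32 to 2.88; 1.09 with at most 50000 fragments) and Csf1r 2.14 (1.51 to 3.03). The osteoclast differentiation and function list had a median log2 ratio of 0.16 (percentile 70.0), the myeloid transcription factors 0.21 (percentile 83.5) and the dendritic cell list 0.01 (percentile 42.5), and no other list had 3 members deep enough.

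In pro- and pre-B cells, B cell genes were less accessible and neutrophil genes more accessible in Irf8cKO. The B cell list had a median log2 ratio of -0.53 (percentile 0), with 4 of 14 members over 1.5 times lower, among them Rag1 at 0.568 (0.471 to 0.681) and Pax5 at 0.628 (0.589 to 0.668), while Ebf1 had 0.651 (0.616 to 0.687). Late granule genes had a median of 2.75 (percentile 100), with Ltf at 14.9 (11.3 to 19.9) and S100a8 at 11.0 (7.82 to 15.8). From the late granule genes, neutrophil fragments were estimated at 36.8% of the fragments of these Irf8cKO droplets. In the cells of each library below the median share of late granule fragments, the B cell list had 0.06 and the ratios were nearer 1, with 0.995 for Pax5 and 0.867 for Rag1.

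Other lists outside the random range in this class were monocyte and macrophage (0.74, percentile 100), AP-1 (0.31, percentile 99.3), MHC class II presentation (-0.33, percentile 1.58) and dendritic cell (-0.37, percentile 0.74). Below the median share of late granule fragments the MHC class II list had 0.02, the dendritic cell list 0.04 and Irf8 a ratio of 1.07. The AP-1 list turned to -0.01 with no upper limit, where 9 members were deep enough (0.02 with the 10 members used otherwise). The late granule list turned to -0.06 with at most 50000 fragments, where 3 of its 13 members were deep enough. Over all cells of the class Irf8 had a ratio of 0.685 (0.621 to 0.755) and Csf1r 2.91 (2.52 to 3.36). The lowest ratios included Cfap74 (0.0730, 0.0454 to 0.111), whose window overlaps Gabrd and Tmem52, and Igsf21 (0.138, 0.102 to 0.184; 0.512 in promoter windows).

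In the erythroid class, the erythroid list had a median log2 ratio of -0.53 (percentile 0.03), with 4 of 11 members over 1.5 times lower. The median was -0.22 when each cell was thinned to 2000 fragments and -0.16 in the cells below the median share of late granule fragments. Gata1 and Klf1, transcription factors of red cell development, had ratios of 0.627 (0.466 to 0.830) and 0.639 (0.498 to 0.810), and Slc4a1, the anion exchanger of the red cell membrane, 0.693 (0.609 to 0.787). AP-1 genes (0.72, percentile 99.5), MHC class I presentation (0.38, percentile 99.6), myeloid transcription factors (0.38, percentile 97.8) and negative regulators of osteoclast differentiation (0.62, percentile 98.5) lay above the random range, the last with -0.26 in the cells below the median share of late granule fragments. Neutrophil fragments were estimated at 35.4% of the fragments of these Irf8cKO droplets. Csf1r had a ratio of 4.46 (3.14 to 6.30), which in the cells below the median share rested on 1 Irf8cKO and 28 WT fragments (0.215, 0.00527 to 1.30). Irf8 had 1.31 (0.695 to 2.32), and 0.343 with at most 50000 fragments.

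Csf1r (gene ID 12978), whose regulatory sequence drives Cre, had a higher whole-gene fragment level in Irf8cKO in each of these 6 classes. In erythroid cells below the median share of late granule fragments a difference was not detectable at this depth. Over all kept cells the difference lay in a window of 7000 bp around the gene start, at chromosome 18 from 61102573 to 61109572, within and upstream of the gene (61105572 to 61131139). The window ratio was then 3.49 (3.36 to 3.63), and the rest of the gene had 0.678 (0.626 to 0.733). In neutrophils the window had 3.10 (2.92 to 3.29) and the rest of the gene 0.845 (0.739 to 0.968), and in promyelocytes 4.01 (3.59 to 4.49) and 1.16. In promyelocytes the sequence upstream of the window, from 61090573, was also higher (3.42, 2.20 to 5.54; 128 cut sites against 24), while in neutrophils it had 1.10. Pro- and pre-B cells had 4.71 (4.18 to 5.32) and 0.465 (0.346 to 0.617), and erythroid cells 23.1 (15.1 to 36.2) and 0.447 (0.209 to 0.849). Both latter classes held the neutrophil fragments described above. The window ratio was 2.15 (1.44 to 3.09) in monocytes and 3.33 (2.47 to 4.50) in stem and early progenitor cells. Outside these 6 classes it was 7.31 (3.69 to 15.5) in T and NK cells and 7.66 (3.66 to 16.9) in basophils and mast cells. Clusters 15 and 18 had 4.33 (2.46 to 7.21) and plasmacytoid dendritic cells 3.64 (1.30 to 8.24). Neutrophil fragments were not estimated in these other classes.

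**Figure D5:**
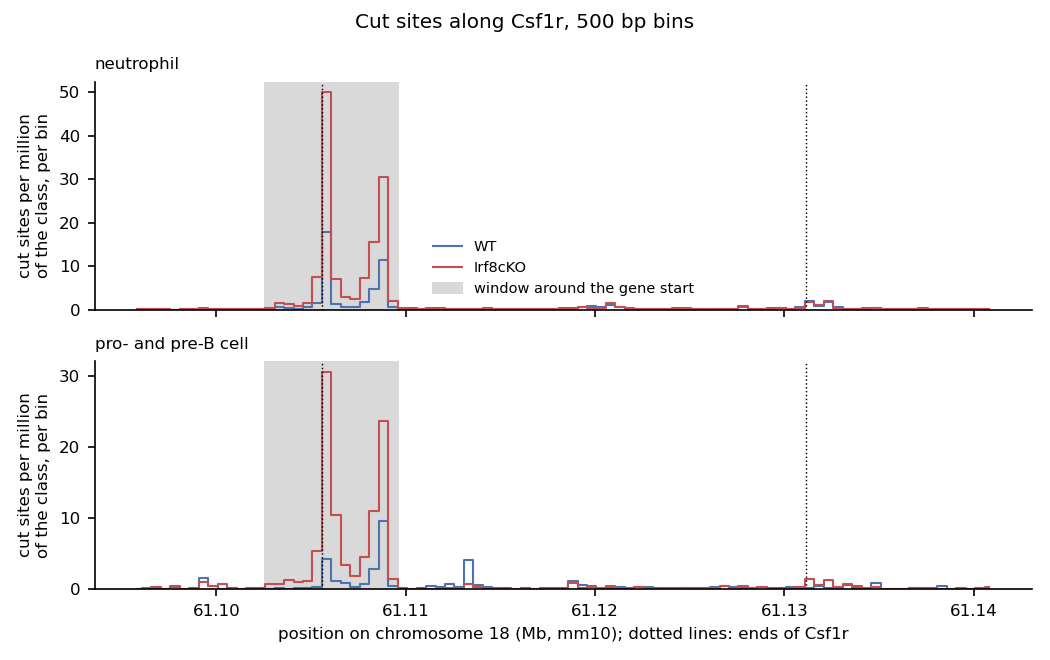
Cut sites per 1000000 cut sites of the class, in 500 bp bins (y axis), along chromosome 18 in Mb (x axis), for WT and Irf8cKO in neutrophils and in pro- and pre-B cells. Irf8cKO is higher inside the shaded 7000 bp around the gene start in both classes.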

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

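A pair of signals lay outside the cells used for the comparisons and above the WT level. Neither was tested for a cause. The Irf8cKO library had 169 barcodes with over 100000 fragments and a TSS enrichment of at least 4, which held 36.2% of its fragments, against 47 barcodes and 9.56% in WT. When these barcodes were kept and clustered with the others, 80 of the Irf8cKO ones fell into the promyelocyte class (19 in WT) and 57 into clusters without a name (2 in WT). The promyelocyte class was the largest among these barcodes in both libraries, so its higher count in Irf8cKO also follows from the larger number of such barcodes.

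Barcodes not kept as cells held 7 of the 9 Irf8cKO fragments that span the empty stretch of Irf8, against 0 in WT. Of these, 6 were in barcodes with over 100000 fragments and 1 in a barcode with under 2000. The other 2 were in kept cells, 1 in the stem and early progenitor class and 1 in the pro- and pre-B cell class.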

How the results depend on the processing

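The alternatives with no upper limit on fragments, with at most 50000 fragments, with ratios within clusters, finer clusters and the clusters of other settings, and with the cells lowest in late granule fragments were chosen after seeing the data. No paired analysis was possible because each group is 1 library of different mice. Of 113 comparisons of 14 cell counts, shares and Irf8 values with their alternatives, 100 stayed within the interval of the reported value (counts, which have none, within 1.5-fold), 12 moved beyond it and 1 reversed. For 77 list medians the counts were 970, 183 and 14 of 1167, and for 76 named genes 894, 278 and 16 of 1188. Some of these comparisons could not change. The filter of at least 50 gene fragments does not enter a gene ratio, so its 76 comparisons stayed the same by construction. The Irf8 stretch was chosen as empty in Irf8cKO, so its Irf8cKO count was 0 in each setting. Reversed counts only lists outside the random range and genes with an interval that excludes 1. With the others included, 189 medians and 27 gene ratios changed direction. The granulocyte share ratio was at least 1.79 in each of 9 settings. The class of promyelocytes did not exist in the space fitted on WT cells, and promyelocytes, monocytes and erythroid cells had no cluster with 20% of its cells from each library. Ratios within clusters were not possible for monocytes and stem and early progenitor cells, each a single cluster. The 3 alternatives on peaks and motifs were not run, since no genome sequence was used. The cause of the differences below was not tested, except where stated.

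Share ratios, Irf8cKO over WT, moved as follows. Promyelocytes had 5.57 and neutrophils 1.69 with at least 5000 fragments, where the mostly WT cluster was named neutrophil, and 3.35 and 1.61 with no upper limit. At resolution 2, promyelocytes had 2.51. With the space fitted on WT cells, monocytes had 0.115, and 0.501 outside the granulocyte classes. At resolution 2, pro- and pre-B cells had 0.324, and 1.19 outside the granulocyte classes. With no upper limit they had 0.284 and 0.811, the latter reversed, and erythroid cells outside the granulocyte classes 0.522. With at most 50000 fragments, WT had 62 cut sites in the Irf8 stretch.

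In monocytes, the space fitted on WT cells gave Mitf 0.951 and F13a1 0.891, both reversed. Promoter windows gave medians of 0.30 for AP-1 and 0.15 for Toll-like receptor genes, both reversed, and 0.34 for monocyte and macrophage and 1.10 for osteoclast genes. Thinning to 2000 fragments gave Toll-like receptor genes 0.60, Mitf 0.790 and F13a1 0.324, all reversed, and osteoclast genes 0.86.

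In neutrophils, the late granule median was 0.033 with at least 5000 fragments, 0.044 at resolution 2, 0.052 with no upper limit, 0.055 thinned and 0.23 in clusters shared by both libraries. It reversed to -0.027 in the space fitted on WT cells, where the class held all granulocytes, and to -0.0068 within clusters. The osteoclast median was -0.051 in promoter windows and 0.11 thinned.

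In promyelocytes, the late granule median was -0.048 within clusters, and it reversed to 0.018 with at least 5000 fragments, where Ly6g had 1.10, and to 0.23 with no upper limit, where Myo18b had 0.911 and F13a1 0.949. The monocyte and macrophage median was -0.028 at resolution 2, 0.28 in promoter windows, -0.18 thinned, 0.27 with genes of at least 50 fragments and 0.27 within clusters. The osteoclast median was 0.20 at resolution 2, 0.0023 in promoter windows and 0.43 thinned. It reversed to -0.014 with at most 50000 fragments, where 11 members were deep enough, and was 0.02 there with the 15 members used otherwise. Klf4 reversed to 0.407 when thinned. Within clusters, Myo18b (0.812) and Ephb2 (0.890) reversed with no upper limit, and Irf8 (0.392), Tgm6 (0.252), Ephb2 (0.233) and Dusp22 (0.560) with at most 50000 fragments.

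In pro- and pre-B cells, the B cell median was -0.17 at resolution 2, -0.21 with no upper limit, -0.23 with at most 50000 fragments, -0.049 thinned and -0.60 in clusters shared by both libraries. In the cells lowest in late granule fragments it reversed to 0.064, as did MHC class II genes (0.022), dendritic cell genes (0.040) and Irf8 (1.07). AP-1 genes reversed to -0.0073 with no upper limit, where 9 members were deep enough, and had 0.023 with the 10 members used otherwise. The late granule median reversed to -0.064 with at most 50000 fragments because only 3 members were deep enough, and was 2.76 with the 13 members used otherwise.

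In erythroid cells, the erythroid median was -0.26 in the space fitted on WT cells, -0.70 with no upper limit, -0.22 thinned and -0.16 in the cells lowest in late granule fragments. In those cells negative regulators of osteoclast differentiation reversed to -0.26 and Csf1r, from 1 Irf8cKO fragment, to 0.215.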

Other observations

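Neutrophil clusters with shared leading genes were split by library, and whether they were at the same stage was not tested. Clusters 4 and 10 were both led by the granule genes Ltf and Ngp, but the share of cells in Irf8cKO over that in WT was 9.55 (6.58 to 14.3) for cluster 4 and 0.107 (0.0523 to 0.198) for cluster 10. Cluster 10 also had Asns and Bmpr1a among its leading genes, and cluster 4 had neither. The 32 WT cells of cluster 4 were shallow, with a median of 5662 fragments against 21322 in Irf8cKO, so depth differs there too. The clusters led by Il1b, which encodes an inflammatory cytokine, also went both ways, with 8.23% of WT and 12.4% of Irf8cKO cells in cluster 0 and 7.64% and 3.86% in cluster 5.

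Genes that differed in the granulocyte classes did not all differ the same way elsewhere. Within the pro- and pre-B and erythroid classes, Asns had a ratio of 1.12 (0.827 to 1.53) and Bmpr1a 1.26 (0.935 to 1.69), against 0.251 and 0.305 in promyelocytes. Tmem178 had 1.82 (1.28 to 2.60) there, taken over both classes. The Irf8cKO droplets of these classes held an estimated 36.8% and 35.4% neutrophil fragments, which changes such ratios.

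The tests of transgene copies, of a strain variant and of free fragments, the finer clusters, the check with separate sets of late granule genes and the B cell list in the cells lowest in late granule fragments were chosen only after the results had been seen. The first 3 of these replaced earlier forms, which decide nothing here. For transgene copies that was the window ratio over all cells of a class (3.10 in neutrophils), which repeats the pattern. The lowest class ratio was 2.15 (1.44 to 3.09), in monocytes. For the strain variant, the genes were compared without allowance for dilution, and then in 2 parts split by outcome. For free fragments, a test set beforehand took the same genes to choose the cells and to give the ratio (1.71).

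The raised Csf1r window is the first pattern. Neutrophil fragments in droplets of other cells did not account for the window in the pro- and pre-B cells lowest in late granule fragments. There observed window cut sites were 3.57 times (3.13 to 4.06) those expected from such a mixture. They were 3.97 and 3.07 times when separate sets of 8 late granule genes chose the cells and gave the share. Over all pro- and pre-B cells they were 1.595 times those expected (lower limit 1.491), so there such fragments stay open as a source of a part. In the erythroid class observed cut sites were 1.26 times (1.03 to 1.51) those expected, so there such fragments stay open. Extra copies of Csf1r regulatory sequence in the Cre transgene, which need a raised window in each class, stay open too. The window ratio of erythroid cells below the median share was 1.22 (0.130 to 5.72), from 2 cut sites in Irf8cKO. Over all kept cells, scaled cut site levels of the outermost bins inside the window were 0.369 against 0.119 in WT and 2.11 against 0.612. In the bins just outside they were 0.0671 against 0.0640 and 0.291 against 0.192. The window was defined from its raised bins, so these edges are no separate test of such copies. An effect of Irf8 loss on Csf1r itself stays open and untested, and the raised sequence upstream of the window in promyelocytes (3.42) was not tested.

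The second pattern is the 10 genes with the highest promyelocyte ratios, Irf8 included. Different clusters within the class stay open: 9 of the 10 genes kept a lower limit above 1.5 within clusters (median ratio 5.26), which met the bound set beforehand against them, but finer clusters of the same cells left 4 (median 2.35) and clusters made with at most 50000 fragments left 0, so that bound did not remove differences inside the clusters. A strain or donor variant shared by all cells, acting alike in each class, was set against ratios in pro- and pre-B and erythroid cells. For 8 of the 10 genes (all but Htra3 and Shisa2) the upper limits there lay below the promyelocyte lower limit. This allowed for dilution by neutrophil fragments (10 of 10 without that allowance). The genes were chosen for high promyelocyte ratios, which also describe clusters within the class, so this test cannot decide and the variant stays open. Tmem178 (1.82), Htra3 (1.71), Shisa2 (1.42) and Myo18b (1.37) were also raised there, so a part shared by all cells, or a variant acting only in granulocytes, stays open. An effect of Irf8 loss was not tested, since the state of the gene was not detectable in promyelocytes, and stage, mouse and batch stay open too.

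For the third pattern, neutrophil late granule genes in pro- and pre-B cells, free neutrophil fragments in all droplets stay open, since the cells lowest in 1 set of late granule genes had 1.11 times (0.958 to 1.28) the WT level of the other set, and 3.95 times (3.13 to 5.00) with the sets exchanged. Droplets that also held a neutrophil nucleus could account for a part, since the 10% of Irf8cKO cells highest in late granule share held 27.9% of late granule fragments and 13.5% of all gene fragments. Even spreads drawn at random in proportion to depth, each with its own top 10% of cells, gave 6.90%. In WT the corresponding values were 32.6%, 10.5% and 10.7%. The top 10% of Irf8cKO cells had a median depth of 53843 fragments, against 35421 in the others. In WT these depths were 22022.5 and 25025. The difference between libraries was not tested, and the explanation by droplets with a neutrophil nucleus stays open. The lower B cell list in this class may be dilution by neutrophil fragments of either source, with a median of 0.06 in the cells lowest in late granule fragments.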
